A study of Bos taurus with 4 samples.

How the data were processed

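Open chromatin was profiled by ATAC-seq, in which a transposase cuts accessible DNA and adds sequencing adapters to it, in the rumen of Holstein cattle. The samples were 2 libraries of male fetal rumen at 90 days and 2 libraries of male adult rumen at 2 years, called fetal 1, fetal 2, adult 1 and adult 2 after the replicate numbers in the labels. Nothing in the labels says that the replicates of a group came from separate animals, so p-values and the spread between replicates measure only these samples and may be technical.

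The authors deposited 1 peak list per library, and peaks were therefore called on each library alone. Each row gives a peak's chromosome, start, end and summit, together with 3 measurements and a score. The fold enrichment, per the narrow-peak layout of the deposited lists, is a ratio of the fragment pileup at the summit to a local background, and it is the authors' own value. The −log10 p and −log10 q values are those the authors' caller gave, and the lowest −log10 q in each deposited list lay between 1.30 and 1.31, so the highest q-value in any list was 0.050. The deposited score equalled 10 times −log10 q, without its decimals, in all rows of fetal 1 and in all but 3, 2 and 4 rows of fetal 2, adult 1 and adult 2. The aligner, peak caller, filters and genome build used for the ATAC-seq data are not given in the sources used here. The tools in the submitters' processing notes are FastQC 0.11.5, Trimmomatic 0.36, Bismark 0.16.3 and Bowtie2, and the extraction text in the labels' protocols describes bisulfite libraries; how the ATAC-seq libraries were made is not given in the sources used here.

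The pileup behind each peak was recovered from the deposited values. A pileup k and an expected pileup m were sought such that the fold equals (k + 1)/(m + 1) and the p-value equals the Poisson probability of more than k fragments at mean m. A whole-number k matched the deposited p within a relative tolerance of 0.0001 for 100% of peaks in each of the 4 lists. The most frequent expected pileup in a list, which was also its lowest to 3 digits, was taken as its genome-wide background. On simulated values the same code recovered 100% of 1993 pileups. This recovery was chosen after the files had been examined. Total read numbers are not in the peak lists, so the depth of each library is known only through this background. A pileup counts fragments over a base, so the background also depends on fragment length, which was not measured. Intervals and expectations cover counting error only, since fragments amplified by PCR are not independent molecules.

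All peaks of the 4 lists were merged where they overlapped by at least 1 bp, and a merged region was counted as open in a library if a peak of that library lay in it. Adult-specific regions carried a peak in both adult libraries and in neither fetal library, fetal-specific regions the reverse, and shared regions a peak in all 4. Regions on the 29 autosomes and X are called chromosomal, and those on unplaced scaffolds are given separately. On simulated lists with 300 planted adult-specific, 60 fetal-specific and 150 shared regions, the code found each of these numbers. Chance overlap between lists was estimated from 100 random circular shifts of one list along each chromosome, with the furthest peak end in any list as the chromosome's length. Shares carry 95% Wilson intervals, odds ratios the conditional 95% intervals that belong to Fisher's exact test, and a difference of shares Newcombe's 95% interval.

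The number of regions that fetal coverage would miss was computed from the lower of the 2 adult enrichments (pileup over expected pileup) at each region open in both adult libraries. The fetal pileup was taken as Poisson with that enrichment times the expected fetal pileup, and a region as called when its p reached the weakest p in the fetal list; the SD is that of independent calls. A region counted as callable when each fetal library had a probability of at least 95% of calling it. On simulated libraries 17.2% of regions were missed where 16.9% were expected. Those libraries were drawn from the same Poisson model with known enrichments, so this checks the code and not whether the model holds for the data. The recurrence of adult regions on X was also tested by drawing windows of 1000000 bp with replacement 1000 times.

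With 2 libraries against 2 there are 6 splits, so the smallest two-sided p of an exact permutation test is 0.333, and no comparison between the groups can pass 0.050 under that test.

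Coordinates are those of the deposited lists, 1-based, on the authors' build. The gene table at hand follows assembly ARS-UCD2.0, while no source names the build of the lists, so no peak was assigned to a gene. The comparisons that need an annotation or a genome (promoter share, genes with group-specific promoter peaks, 20 gene lists and 22 sequence motifs) were not analysed here. The rule for named regions, fixed before the data were examined, took the first 5 adult-specific and the first 5 fetal-specific regions by the lower of the 2 replicates' fold enrichments; it was written for regions away from transcription start sites and was applied to all chromosomal regions, since start sites were not used here. Other regions named below were chosen after their values were seen.

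The alternatives fixed before the data were examined were a −log10 q of at least 5, the same number of peaks per library (the 1878 strongest, the length of the shortest list), either replicate in place of both, a cover of at least 50% of the merged region, leaving out each library, and the chromosomes alone. Alternatives added after seeing the data left out the first 1000000 bp of each chromosome, joined regions within 100000 bp, or used the higher of the 2 adult enrichments. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.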

Results

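Chromatin accessibility was compared between fetal rumen, the forestomach chamber at an early stage, and adult rumen. The series title places this comparison within the question of how the rumen acquires its tissue-specific functions. The 4 lists held 1878 peaks for fetal 1, 2788 for fetal 2, 8795 for adult 1 and 13934 for adult 2. Fetal libraries thus averaged 2333 ± 643 peaks (SD, n = 2) and adult libraries 11365 ± 3634 (SD, n = 2), and each adult list was longer than each fetal list. The exact two-sided permutation p was 0.333, the smallest that 2 against 2 libraries allow.

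The adult libraries were covered more deeply. The background pileup is the most frequent expected pileup among the peaks of a list, in fragments over a base. It was 0.495 in fetal 1 and 0.426 in fetal 2, against 1.37 in adult 1 and 1.61 in adult 2. At that background the weakest called peaks held 5 fragments in each fetal library and 8 in each adult library. These correspond to enrichments over background of 10.1 in fetal 1, 11.7 in fetal 2, 5.84 in adult 1 and 4.97 in adult 2. These are the lowest observed enrichments that were called, not limits on the enrichment of a region. A region of lower enrichment over plain background was called only where its pileup happened to reach that number of fragments. Fetal peaks were wider, with median widths of 305 bp and 190 bp against 98 bp and 116 bp in the adult lists. The narrowest peaks measured 186 bp in fetal 1, 112 bp in fetal 2, 67 bp in adult 1 and 81 bp in adult 2. Divided by these widths, the background was 0.00266 in fetal 1, 0.00381 in fetal 2, 0.0204 in adult 1 and 0.0199 in adult 2. On that scale both adult libraries stayed above both fetal ones, but fetal 1 lay below fetal 2, the reverse of their backgrounds. Whether the narrowest width follows fragment length was not tested.

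Unplaced scaffolds, the contigs of the assembly that have no chromosome, held a large part of the peaks in each library. They carried 71.3% of the peaks of fetal 1 (95% interval 69.2 to 73.3) and 65.7% of those of fetal 2 (64.0 to 67.5). In adult rumen the share was 46.3% in adult 1 (45.2 to 47.3) and 35.7% in adult 2 (34.9 to 36.5). Scaffold peaks were also the strongest, with a median fold enrichment of 8.73 in fetal 1, 8.41 in fetal 2, 7.87 in adult 1 and 7.21 in adult 2. On the autosomes the medians were 4.61, 4.72, 4.22 and 4.02 in the same order. The autosomes and X held 539 and 955 fetal peaks and 4725 and 8961 adult peaks. The highest pileup was 4432 fragments in fetal 1, 3151 in fetal 2, 4079 in adult 1 and 4799 in adult 2. Library quality and sequence copies collapsed in the assembly were not tested, so an open region means only that a peak was called there.

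**Figure D1:**
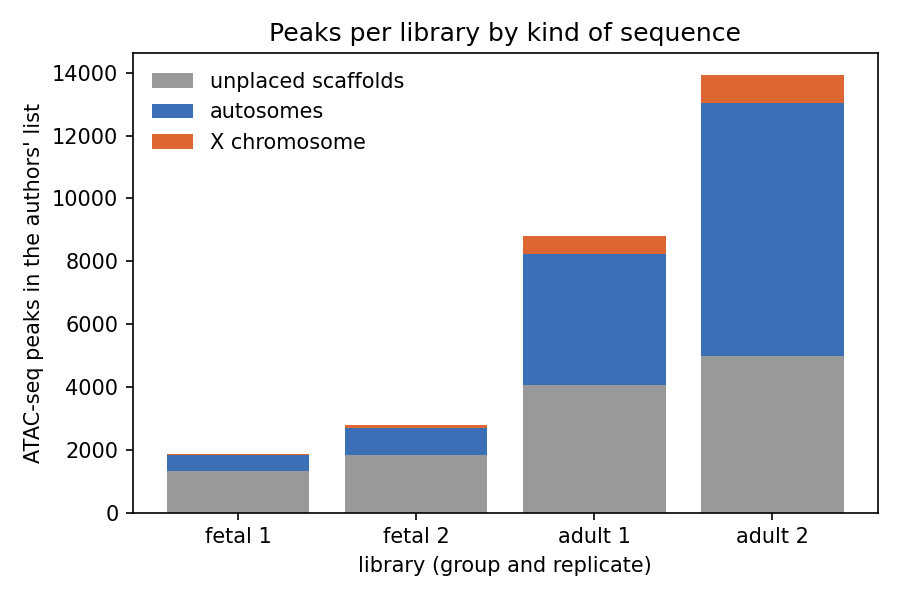
Number of peaks in each deposited list (y axis) for the 4 libraries (x axis), stacked by unplaced scaffolds, autosomes and X; 1 bar is 1 library, without error bars. The lists grow from 1878 peaks in fetal 1 to 13934 in adult 2, and scaffolds make up 71.3% of the former and 35.7% of the latter.

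In the full lists, which differ in length, replicates shared few of their chromosomal peaks. Of the 539 chromosomal peaks of fetal 1, 135 (95% interval 21.6 to 28.9%) overlapped a peak of fetal 2. Of the 4725 of adult 1, 810 (17.1%, 16.1 to 18.2) overlapped one of adult 2. Both numbers lay far above the overlap of randomly shifted lists, which averaged 0.16 peaks for the fetal pair and 4.58 for the adult pair and reached at most 3 and 14. Between the groups 28.0% (24.4 to 32.0) of fetal 1 chromosomal peaks overlapped adult 1 and 28.4% (24.7 to 32.3) adult 2. For fetal 2 these shares were 26.4% (23.7 to 29.3) and 27.6% (24.9 to 30.6). With the 1878 strongest peaks of each library, 205 of 272 chromosomal peaks of adult 1 (75.4%, 69.9 to 80.1) overlapped adult 2 and 195 of 226 of adult 2 (86.3%, 81.2 to 90.2) overlapped adult 1. The chromosomal parts of these cut lists were unequal, with 539 peaks in fetal 1 and 275 in fetal 2. At that length the overlap, as a share of the shorter chromosomal list, was 48.4% for the fetal pair (23.0% of the 539 of fetal 1) and 43.8% to 64.6% between the groups. On scaffolds it was 75.4% for the fetal pair, 83.9% for the adult pair and 51.8% to 65.2% between the groups. In the full lists on scaffolds the fetal replicates shared 80.1% of the peaks of fetal 1 and the adult replicates 81.4% of those of adult 1, while between the groups 75.5% and 81.1% of the peaks of fetal 1 overlapped adult 1 and adult 2, and 79.4% and 84.0% of those of fetal 2.

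Strong peaks recurred more often than weak ones. Among autosomal peaks of adult 1 with −log10 q under 3, 45 of 2352 (1.91%, 1.43 to 2.55) were found in adult 2, against 376 of 429 (87.6%, 84.2 to 90.4) of those at 10 or more. In fetal rumen 4 of 296 autosomal peaks of fetal 1 under 3 were found in fetal 2 (1.35%, 0.527 to 3.42) and 67 of 69 at 10 or more (97.1%, 90.0 to 99.2). In the other direction 72 of 104 autosomal peaks of fetal 2 at 10 or more were found in fetal 1 (69.2%, 59.8 to 77.3), and 373 of 428 of adult 2 in adult 1 (87.1%, 83.6 to 90.0). Strong chromosomal peaks of fetal rumen were also found in adult rumen: of the 81 in fetal 1 at 10 or more, 74 overlapped adult 1 and 76 overlapped adult 2.

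**Figure D2:**
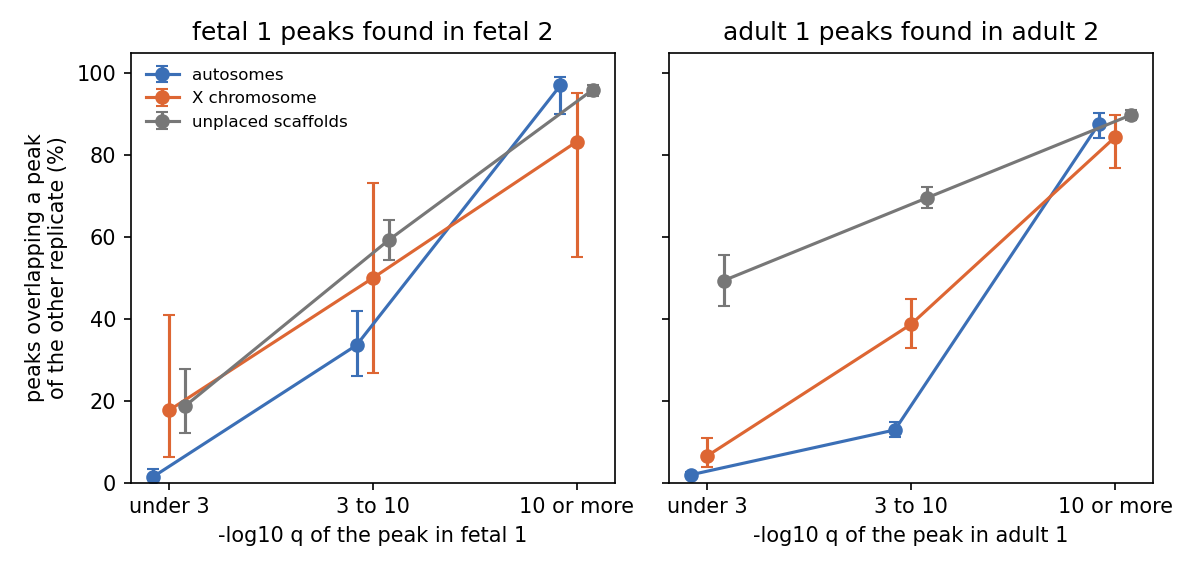
Percent of peaks of replicate 1 that overlap a peak of replicate 2 (y axis) by the −log10 q of the replicate 1 peak (x axis, 3 ranges), for fetal rumen on the left and adult rumen on the right; points are shares, bars 95% Wilson intervals, and lines join the same kind of sequence. Autosomal recurrence in adult rumen goes from 1.91% in the weakest range to 87.6% in the strongest.

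Merging gave 19749 regions, of which 13891 were chromosomal. Of the chromosomal regions 488 were adult-specific, 7 were fetal-specific and 118 were open in all 4 libraries, while 13125 (94.5%) carried a peak in 1 library alone. The adult-specific regions lay on all 29 autosomes (335 regions) and on X (153 regions). The 7 fetal-specific regions were autosomal. With equally long lists of 1878 peaks the chromosomal numbers were 51 adult-specific, 24 fetal-specific and 85 shared. Those lists were equal over all sequences only. Their chromosomal parts held 539 peaks in fetal 1, 275 in fetal 2, 272 in adult 1 and 226 in adult 2. The cut also removed adult peaks, which can turn a region of the full lists into a fetal-specific one. Single libraries moved the numbers further, and without a library its group rested on the other library alone. The adult-specific number was 8675 without adult 1 and 4417 without adult 2, the fetal-specific number 687 without fetal 1 (against 515 adult-specific regions there), 378 without fetal 2 and 12 without adult 2, and the shared number 227 without fetal 1.

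Scaffolds held 1601 adult-specific, 81 fetal-specific and 881 shared regions, and 2511 of their 5858 regions (42.9%) carried a peak in 1 library alone. With equally long lists the adult-specific and fetal-specific numbers were 390 and 254. Without adult 1 or adult 2 there were 3214 and 2402 adult-specific regions, the fetal-specific number was 223, 203, 122 and 150 without fetal 1, fetal 2, adult 1 and adult 2, and 1352 regions were shared without fetal 1.

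**Figure D3:**
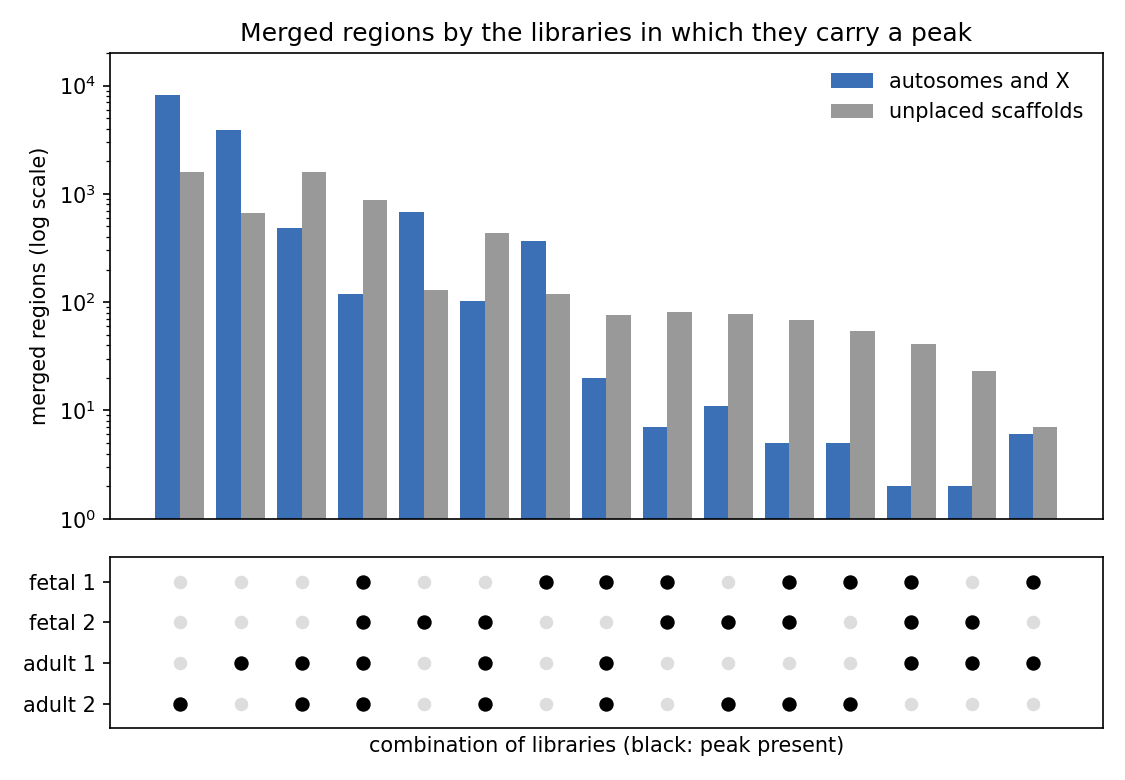
Number of merged regions (y axis, log scale) for each combination of libraries in which they carry a peak (x axis; black dots mark the libraries), with chromosomal and scaffold regions as separate bars. Regions of adult 2 alone are the most numerous chromosomal class (8179), 488 chromosomal regions carry peaks in both adult libraries alone and 7 in both fetal libraries alone.

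The strongest chromosomal adult-specific region lay on chromosome 21 from 68450702 to 68450827, with a fold enrichment of 67.8 in adult 1 and 56.0 in adult 2 and pileups of 272 and 303 fragments. It was followed by a region on chromosome 28 from 624009 to 624091, at 59.3 and 47.2, and one on chromosome 4 from 203565 to 203662, at 44.3 and 35.8. A pair of neighbouring regions on chromosome 25 came next. The first, from 35733891 to 35734200, had 33.8 in adult 1 and 43.9 in adult 2. The second, from 35733511 to 35733776, had 32.5 and 41.9. The top 3 were 126, 83 and 98 bp wide, and the chromosome 25 pair 310 and 266 bp.

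Among the 7 chromosomal fetal-specific regions the strongest lay on chromosome 7 from 20389899 to 20390134, with 13.7 in fetal 1 and 22.3 in fetal 2 and pileups of 62 and 82 fragments. The next was on chromosome 13 from 71899416 to 71899661, at 12.5 and 9.60. Weaker ones lay on chromosome 16 from 184056 to 184333 (6.63 and 6.01), on chromosome 17 from 73139491 to 73139814 (10.8 and 5.53) and on chromosome 18 from 60907 to 61125 (5.02 and 5.34). What these positions hold in the gene annotation was not analysed here.

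The strongest chromosomal regions open in all 4 libraries were named after their values were seen. On chromosome 7 from 120114 to 120662 the fold was 31.7 in fetal 1, 50.5 in fetal 2, 87.5 in adult 1 and 84.4 in adult 2. On chromosome 21 from 33002482 to 33002912 it was 28.4, 36.5, 71.5 and 68.4. The strongest shared region of X, from 28354156 to 28354776, had 20.0, 28.5, 57.6 and 49.9. The deposited folds equal a ratio with 1 added to pileup and background, which lowers them more at low coverage, so they rank regions within a list and do not measure a change between the groups.

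The first 1000000 bp of some autosomes, and not of X, were rich in recurring regions. Over the autosomes and X together these parts held 74 of 539 chromosomal peaks in fetal 1 (13.7%, 11.1 to 16.9), 128 of 955 in fetal 2 (13.4%, 11.4 to 15.7), 333 of 4725 in adult 1 (7.05%, 6.35 to 7.81) and 424 of 8961 in adult 2 (4.73%, 4.31 to 5.19). Among recurring chromosomal regions the share was 25.2% (21.6 to 29.2) of the 488 adult-specific, 4 of the 7 fetal-specific and 35.6% (27.5 to 44.6) of the 118 shared regions. On the autosomes alone these parts held 36.4% (31.4 to 41.7) of the 335 adult-specific and 42.0% (32.8 to 51.8) of the 100 shared regions, against 1 of 153 and 0 of 18 on X. They were unevenly spread: the first 1000000 bp of chromosomes 13, 16 and 28 held 24, 19 and 11 adult-specific regions, and 8 of the 29 autosomes had none there.

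Most chromosomal regions open in both fetal libraries were also open in adult rumen. Of 132 chromosomal regions open in both fetal libraries, 120 were open in adult 1 (90.9%, 84.8 to 94.7) and 123 in adult 2 (93.2%, 87.5 to 96.4). In the other direction, of 728 chromosomal regions open in both adult libraries, 138 were open in fetal 1 (95% interval 16.3 to 22.0%) and 220 in fetal 2 (30.2%, 27.0 to 33.7). Pairs with 1 library of each group gave similar shares where the third library was adult. Of 224 regions open in fetal 2 and adult 1, 220 were open in adult 2 (98.2%, 95.5 to 99.3). Of 146 open in fetal 1 and adult 1, 138 were open in adult 2 (94.5%, 89.6 to 97.2). The shares were lower where the third library was fetal. Of those 146 regions, 120 were open in fetal 2 (82.2%, 75.2 to 87.5). Fetal 1 was open at 120 of the 224 regions (53.6%). It was also open at 123 of 236 regions open in fetal 2 and adult 2 (52.1%). Fetal 1 lacked a peak at 102 of the 220 chromosomal regions that fetal 2 and both adult libraries shared.

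Measured up to the furthest peak of each chromosome, X carried more peaks per length than the autosomes in each library. Adult rumen had 4.10 peaks per Mb of X in adult 1 and 6.39 in adult 2, against 1.67 and 3.25 over the autosomes. These are ratios of 2.45 (2.24 to 2.67) and 1.97 (1.83 to 2.11). Fetal rumen had 0.310 and 0.626 peaks per Mb of X, and the ratios were 1.55 (1.11 to 2.12) in fetal 1 and 1.79 (1.42 to 2.24) in fetal 2. In both fetal libraries chromosome 23 was denser than X, with 0.476 peaks per Mb in fetal 1 and 0.705 in fetal 2. Chromosome 19 had the lowest density in both adult lists, with 0.568 and 2.22 peaks per Mb.

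**Figure D4:**
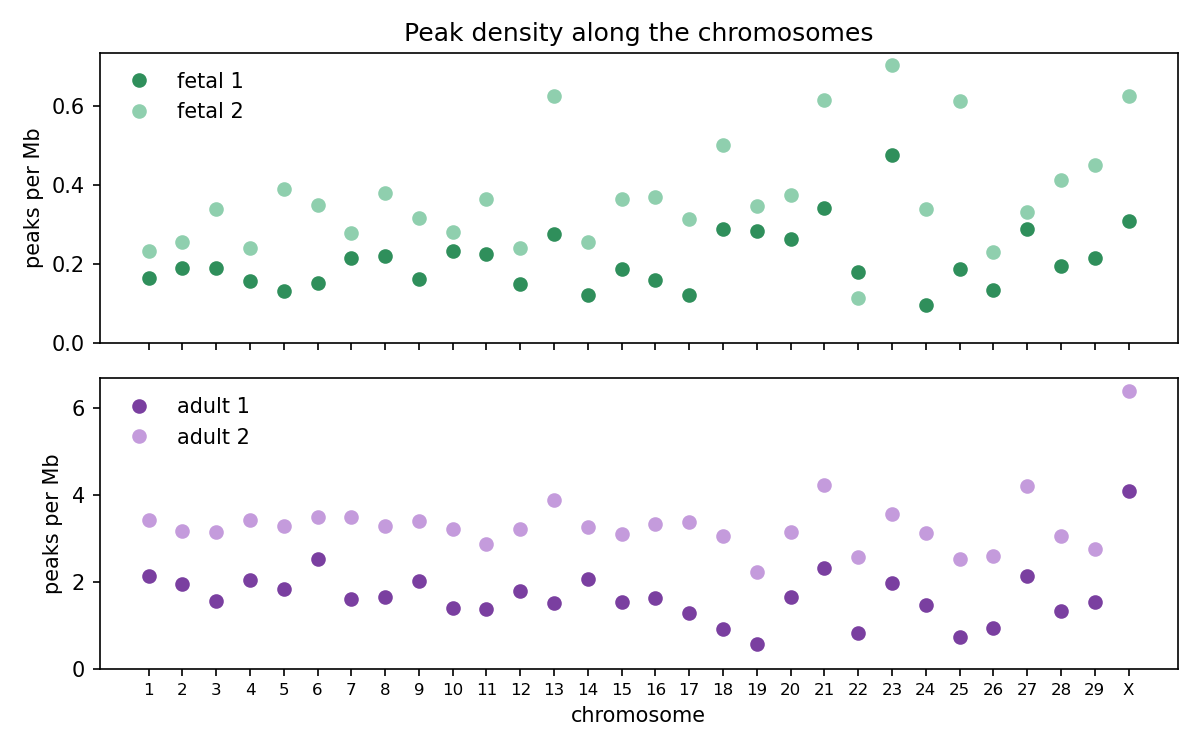
Peaks per Mb (y axis) on each autosome and X (x axis) for the fetal libraries above and the adult libraries below; each point is 1 library and the y axes differ between panels. X has the highest density in both adult libraries (4.10 and 6.39 peaks per Mb) and chromosome 19 the lowest (0.568 and 2.22). In both fetal libraries chromosome 23 has the highest (0.476 and 0.705).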

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

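The alternative without the first 1000000 bp of each chromosome was chosen after the data were examined, as were joining nearby regions and using the higher adult enrichment. The count of adult-specific regions exceeded that of fetal-specific ones on chromosomes and on scaffolds under each alternative that was run except 1: without fetal 1 there were 687 fetal-specific and 515 adult-specific chromosomal regions, with fetal 2 alone standing for the fetal group. With lists equally long over all sequences, but not on chromosomes, they were 51 and 24 on chromosomes and 390 and 254 on scaffolds. With either replicate in place of both they were 12564 and 1056 on chromosomes and 3863 and 330 on scaffolds, with 271 and 1665 regions open in both groups. A −log10 q of at least 5 left 4 and 51 fetal-specific regions on chromosomes and scaffolds, and 1240, 1663, 4243 and 5083 peaks in fetal 1, fetal 2, adult 1 and adult 2. On the autosomes and X alone the full lists held 539, 955, 4725 and 8961 peaks. Asking for a cover of 50% of the region gave 12 and 151 fetal-specific and 77 and 541 shared regions on chromosomes and scaffolds. Without the first 1000000 bp of each chromosome, 3 fetal-specific and 76 shared chromosomal regions were left. Leaving out each library in turn gave 515 to 8675 adult-specific, 9 to 687 fetal-specific and 121 to 227 shared regions on chromosomes, and 1706 to 3214, 122 to 223 and 923 to 1352 on scaffolds; the highest adult-specific and fetal-specific values come with a single library standing for its group. On chromosomes the adult-specific number was 8675 without adult 1 and 4417 without adult 2, and the fetal-specific number 687 without fetal 1 and 378 without fetal 2. Peaks with −log10 q under 3 rarely recur on chromosomes, so such counts rest on calls of 1 library. The odds ratio of recurrence for X against the autosomes was 0.713 (95% interval 0.176 to 2.57) with equally long lists, where 14 regions of X were left, against 4.88 with all peaks. It was 7.54 (6.02 to 9.42) without the first 1000000 bp, 1.86 (1.47 to 2.35) with regions joined within 100000 bp and 1.78 (1.32 to 2.39) with −log10 q of at least 5. No paired analysis was possible because no label pairs a fetal library with an adult one. The counts of regions come from no test, and the lists hold no values for regions without a peak. Fewer peaks explain the lower counts under the stricter limit and equal length by construction; the cause of the other changes was not tested. With the higher adult enrichment fetal coverage was expected to miss 114.5 chromosomal and 201 scaffold regions. The ratios of 7.54, 1.86 and 1.78 are among 24 values that kept their direction and their side of the test or, for counts, stayed within 1.5 times. Most values did not: 41 moved, and 1, the ratio with equally long lists, reversed. The alternatives for promoters, gene lists and motifs were not run, since those results were not analysed here. Fetal coverage limits calls: the lowest observed enrichments called over plain background were 10.1 in fetal 1 and 11.7 in fetal 2.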

Other observations

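The places named here were chosen after their values were seen. The 1000000-bp windows of X with the most adult-specific regions started at 18000001 (23 regions), 28000001 (21 regions), 124000001 (12 regions) and 84000001 (11 regions). Of the adult-specific regions of X the strongest lay from 37920285 to 37920505 (fold 13.5 in adult 1 and 18.4 in adult 2) and from 28502059 to 28502178 (13.1 and 13.0). On the autosomes outside the first windows, chromosome 6 from 5000001 to 6000000 held 22 adult-specific regions and chromosome 21 from 32000001 to 33000000 held 11.

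The tests of coverage, of peak strength on X and of peak width below were set out before their results were seen, while the test that resamples windows on X was chosen after the pattern and the result with joined regions had been seen, and joining regions was itself chosen after the data were examined, as was the check of the coverage expectation within groups, which was added after the excess had been seen and is why coverage is left open.

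Adult-specific regions outnumbered fetal-specific ones, 488 to 7 on chromosomes, an order that turned (515 to 687) without fetal 1. That setting is unequal, since fetal 2 then stood alone for its group while adult-specific regions still needed both adult libraries. With all libraries, 678 chromosomal regions carried a peak in fetal 2 and in no other library. Fetal coverage was expected to miss 186 of the 728 chromosomal regions open in both adult libraries and 488 were missed, 33.5 SD more (77.8 SD on scaffolds, with 1601 missed and 438 expected); of the 185 that both fetal libraries were expected to call, 48 were missed (0.0156 expected), as were 398 of 1277 on scaffolds (0.106 expected), while the other 440 chromosomal misses lay where at least 1 fetal library was not expected to call reliably. This goes beyond counting error, but coverage stays open, since the SD leaves out differences between single libraries and the expectation failed for most of them: of regions open in the other 3 libraries, fetal 1, fetal 2, adult 1 and adult 2 missed 102, 20, 5 and 2 on chromosomes (23.8, 16.5, 0.772 and 0.0113 expected) and 437, 76, 69 and 41 on scaffolds (145.6, 123.6, 13.2 and 6.59 expected); it held for fetal 2 on chromosomes, a library that still missed 508 of the 728 regions open in both adult libraries (301 expected). Another candidate explanation is fragment length, which was not measured: among the 185 regions, narrow adult peaks (284 bp or less in adult 2) were missed in 42 of 94 cases and wide ones in 6 of 91, a difference of 38.1 percentage points (26.1 to 48.8; Fisher's exact test, two-sided p = 1.26e-09), but narrow peaks also had lower pileups (median 82 against 121) and the influence of strength was not separated. The stage of the rumen separates the same libraries as coverage does and stays open, as untested.

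Adult peaks on X recurred more often than those on autosomes: of regions with an adult and no fetal peak, 153 of 1186 on X (12.9%, 11.1 to 14.9) and 335 of 11378 on autosomes (2.94%, 2.65 to 3.27) were open in both adult libraries, an odds ratio of 4.88 (3.96 to 5.99; Fisher's exact test over regions, two-sided p = 6.08e-44). Resampling 1000000-bp windows left a lower 95% bound of 2.59. This cannot decide whether a few dense clusters were the cause, since resampling seldom leaves out all dense windows. The densest windows of X held 23, 21, 12 and 11 of the 153 regions, and the ratio without them was not computed. Joining regions within 100000 bp lowered the ratio to 1.86, but joining also raised recurrence on autosomes to 20.2%, and the overlap that chance gives joined regions was not computed. The values argue against peak strength as the whole cause, since the ratio was 2.15 (1.59 to 2.91) among regions whose strongest adult peak had a −log10 q of at least 5, and regions from 3 to 10 recurred in 16.9% (13.8 to 20.5) of cases on X and 4.07% (3.45 to 4.81) on autosomes. At 10 or more no difference was detected, with 72.9% (63.3 to 80.8) of regions on X and 65.5% (59.8 to 70.8) on autosomes, 84.4% (77.0 to 89.8) and 87.6% (84.2 to 90.4) of adult 1 peaks, and 92.7% (86.2 to 96.2) and 87.1% (83.6 to 90.0) of adult 2 peaks, and the ratio with equally long lists was 0.713 (0.176 to 2.57) on 14 regions of X. Sequence copies collapsed in the assembly stay open and were not tested, and no biological explanation was tested.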
